A study of Mus musculus with 4 samples.

How the data were processed

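The study sequenced poly(A) RNA of bone marrow-derived macrophages from Lyz2Cre+ mice, per the labels' protocols, with oligo(dT) selection, a library kit that does not mark strand and paired 150-base reads on a HiSeq instrument. Reads from overlapping or antisense genes therefore cannot be told apart. The 4 libraries fall into M1 (n = 2) and M2 (n = 2) by their labels, and replicate numbers were given here in accession order, so they pair nothing. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and DESeq, and the genome build was GRCm38; their roles and settings are not given in the sources used here.

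The authors deposited a table of whole-number read counts per gene for the 4 libraries, not normalized. They also deposited a comparison table with a gene symbol and 6 value columns. As its values show, its base mean is a signal, the mean of counts divided by size factors, and the log2 fold change and its standard error are log2 values of M1 over M2 that the authors deposited. The test statistic in it is a score, and the p-value and adjusted p-value are those the authors deposited. The smallest absolute log2 fold change in it is 1.00.

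Gene IDs were matched to GENCODE vM21 on GRCm38: 48970 of 49315 had a symbol, and the 345 without one held 0.0316% to 0.0498% of the counts of a library. Library totals ran from 26806370 to 39506242 counts. The 20 most abundant genes took 14.0% to 14.4% of counts and mitochondrially encoded genes 1.24% to 1.67%. TMM factors were 0.846 and 0.866 for M1 and 1.17 and 1.17 for M2, so scaling differed systematically between groups.

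The comparison was fitted with edgeR 4.0.16 (R 4.3.3): filterByExpr (count threshold 10, total count threshold 15), TMM, robust quasi-likelihood fit and F test, two-sided, Benjamini-Hochberg adjustment, calls at an adjusted p under 0.05. Values per gene are TMM-normalized CPM with SD, and fold changes are M2 minus M1 on the log2 scale. Their standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.0528. A group with no count was set against a floor of 3 counts over the group, and one with 1 to 3 counts was given as a ratio with an exact 95% interval; floors and intervals cover counting error only. Set tests on 30 lists of at least 5 tested genes used camera in limma 3.58.1 with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and 3 of the 33 lists were too small. With 2 libraries per group the estimated version has few degrees of freedom and could hardly call a list. Its lack of calls therefore decides nothing either way. Alternatives included RLE, upper-quartile and total-count scaling, TMM without the 50 most abundant genes, no filter, a CPM filter of 5 in 2 libraries, DESeq2 1.42.0, limma-voom, a non-robust spread, glmTreat beyond log2 1, and each library left out in turn.

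Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named the 10 genes with the largest fitted change each way among called genes of at least 5 CPM in the higher group whose libraries did not overlap, leaving out Gm-number and Rik symbols. It also named up to 2 called members of each list each way with a mean of at least 1 CPM (the 2 most abundant where none was called), and Egfr, Erbb2, Erbb3, Erbb4, Hbegf, Areg, Ereg, Tgfa, Btc, Lyz2, Nos2 and Arg1 always. Chosen after their values were seen were Adgre1, B2m, Ccl17, Cd247, Cd274, Cd74, Chil3, Chil4, Ciita, Cish, Col1a1, Gapdh, Gata2, H2-Ab1, Hba-a2, Il1b, Il4ra, Klf4, Lgals9, Lyrm9, Mcpt8, Mmp12, mt-Co2, Pdk1, Tap1, Tgm2, Tnf and Trem2. The closing observations also name Anxa1, Ccl5, Cd68, Col1a2, Col3a1, Col6a1, Col6a3, Col9a3 and Csf1r, which the rule did not name. The same holds there for Psmb9, Psmd8, Psmd11, Stx11, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. List members under upper-quartile and total-count scaling, and the checks of printed symbols in the authors' deposited table, were added after the data were seen. The comparison of replicates by list, with random lists, was not among the tests fixed beforehand. Some genes that the rule named are not reported here.

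The fit was tested on 10 simulated data sets drawn from the means and library sizes of the 14656 tested genes, each with 200 genes changed. It recovered 64.7% of changes of log2 size 0.5, 81.9% of size 1 and 95.7% of size 2. Unchanged genes made up 5.44% of calls over all 10 sets, from 1.86% to 12.0% in a single set. A first run on 1 of these sets alone gave that highest share, after which the number of sets was raised to 10. A raised list of 20 genes was called in 10 of 10 sets and 0 of 1000 unchanged lists were called. Genes were drawn independently of one another and few were changed. The sets therefore do not show how often lists whose genes move together between replicates would be called. Nor do they give the share of false calls in the comparison itself, where 77.2% of tested genes were called. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.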

Results

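Gene expression was measured by poly(A) RNA sequencing in 4 libraries of mouse bone marrow-derived macrophages, cells that are grown from marrow progenitors in the presence of macrophage growth factors. The marrow came from Lyz2Cre+ mice, which carry the Cre recombinase at the Lyz2 locus and are used to delete genes in myeloid cells. At 7 days of culture the cells were polarized for 24 hours. The 2 M1 libraries come from cells given LPS (100 ng/ml) and interferon gamma (50 ng/ml), the classical inflammatory stimulus. The 2 M2 libraries come from cells given IL-4 (10 ng/ml) and IL-13 (10 ng/ml), the alternative stimulus. The series as a whole concerns polarization with and without erlotinib, an inhibitor of the EGF receptor kinase, and the labels of these 4 libraries do not say whether any received it. No unpolarized library was analysed here, so a gene that is higher in M2 may equally be described as lower in M1, and "higher" and "lower" below refer to M2 against M1.

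The M1 libraries held 34445668 and 28407982 gene counts, and the M2 libraries held 26806370 and 39506242. Of 49315 genes in the count table, 25720 had at least 1 count and 14656 passed the filter on low counts and were tested. The groups stood far apart: the first principal component of log2 CPM (counts scaled to library size with TMM factors) carried 97.3% of the variance and separated M1 from M2. Pearson's r across genes, which are not independent replicates, was 0.994 between the M1 libraries and 0.996 between the M2 libraries, against 0.819 to 0.822 between libraries of different groups. Replicates differed by more than counting noise in both groups, with a chi-square per degree of freedom of 13.6 for M1 and 2.36 for M2. This argues against the same library having been deposited again, but does not show separate samples. Each library was counted as its own sample. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

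The comparison asks which transcripts differ between the inflammatory and the alternative polarization. Interferon-stimulated and inflammatory genes were higher in M1, and most alternative activation and fatty acid oxidation genes on the fixed lists were higher in M2. Nos2, the inducible nitric oxide synthase, had 7646 ± 550 CPM in M1 and 10.1 ± 0.641 in M2 (SD, n = 2 each), a 759-fold difference. Igf1, insulin-like growth factor 1, went the other way, with 2.11 ± 0.115 CPM in M1 and 1248 ± 12.4 in M2, a 587-fold difference. Mrc1, the mannose receptor CD206, was 415-fold higher in M2, and Il6, a pro-inflammatory cytokine, was 797-fold higher in M1. Carry-over between libraries was not excluded, so the few counts in the lower group may not all be expression.

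Of the 14656 genes tested with edgeR's quasi-likelihood test, 11312 (77.2%) differed at an adjusted p under 0.05, 5817 higher and 5495 lower in M2. By at least 1 log2 unit, 3298 of these were higher and 2668 lower, and by at least 5 log2 units 293 were higher and 379 lower. The median size of a called change was 1.08 log2 units and the smallest was 0.13. The balance of directions depended on the scaling: 51.4% of calls were higher in M2 under TMM normalization, 71.9% when libraries were scaled to their total counts and 60.8% under upper-quartile scaling. Total-count scaling moved the median gene upward in M2 by 0.45 log2 units against TMM and upper-quartile scaling moved it by 0.18, so small changes below are relative to the TMM scale. Against a fold change of at least 2 (glmTreat beyond log2 1), 4840 genes were called.

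Among named genes of at least 5 CPM in M2 that did not overlap between groups, the 10 with the largest fitted rises included several with hardly any M1 counts, whose place rests on the fitted value and not on a measured size. Rnase2a, an eosinophil-associated ribonuclease, had no M1 count and 19.4 and 17.4 CPM in the M2 libraries, at least 326-fold higher against a floor of 3 counts over the group. Il31ra, a receptor subunit for the cytokine IL-31, was at least 133-fold higher, Mamdc2 at least 113-fold and the collagen gene Col6a5 at least 105-fold by the same floor. Retnla, the secreted M2 marker Fizz1, had 3 counts in the M1 libraries together and 6125 in the M2 libraries, a ratio of 1420 after scaling (95% counting interval 485 to 6870). Zfyve28 had 3 and 2759 counts (ratio 638, interval 218 to 3100) and Galnt9 had 1 and 692 (ratio 480, interval 85.9 to 19000). Mgl2, a macrophage galactose-type lectin, was 640-fold higher, a fold that rests on 1 and 3 counts in the M1 libraries. Igf1 and Mrc1 were also among the 10, and Atp6v0d2 (360-fold) was not, although its measured fold lies above the floors of Il31ra, Mamdc2 and Col6a5. These intervals and floors cover counting error only.

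In the other direction, the 10 largest fitted falls were Cxcl11, BC023105, Bcl2l14, Gbp2b, Clic5, Cxcl10, Ifi205, Il6, Il12b and U90926. Cxcl11, a chemokine gene induced by interferon, is annotated as a polymorphic pseudogene. It had 205 ± 38.9 CPM in M1 and 0.140 ± 0.0172 in M2 and was 1406-fold higher in M1. BC023105, annotated as a processed pseudogene, was 1389-fold, Bcl2l14 1120-fold and the guanylate-binding protein gene Gbp2b 1112-fold higher in M1. These folds rest on few counts in the M2 libraries: 4 and 7 for Cxcl11, 4 and 5 for BC023105, 5 and 4 for Bcl2l14, and 6 and 7 for Gbp2b. As a ratio of pooled counts, Cxcl11 was 1459-fold higher in M1, with a counting interval of 815 to 2923. That interval takes in all of these folds, so their order is uncertain. Cxcl10 reached 6671 ± 486 CPM in M1 and was 876-fold higher there, and Il12b, a subunit of IL-12 and IL-23, was 783-fold higher with unequal M1 libraries (4501 and 6970 CPM). U90926 had no M2 count and was at least 159-fold higher in M1, so its place rests on the fitted value; Gbp4 (763-fold) and Nos2 (759-fold), with measured folds above that floor, lay outside the 10.

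**Figure D1:**
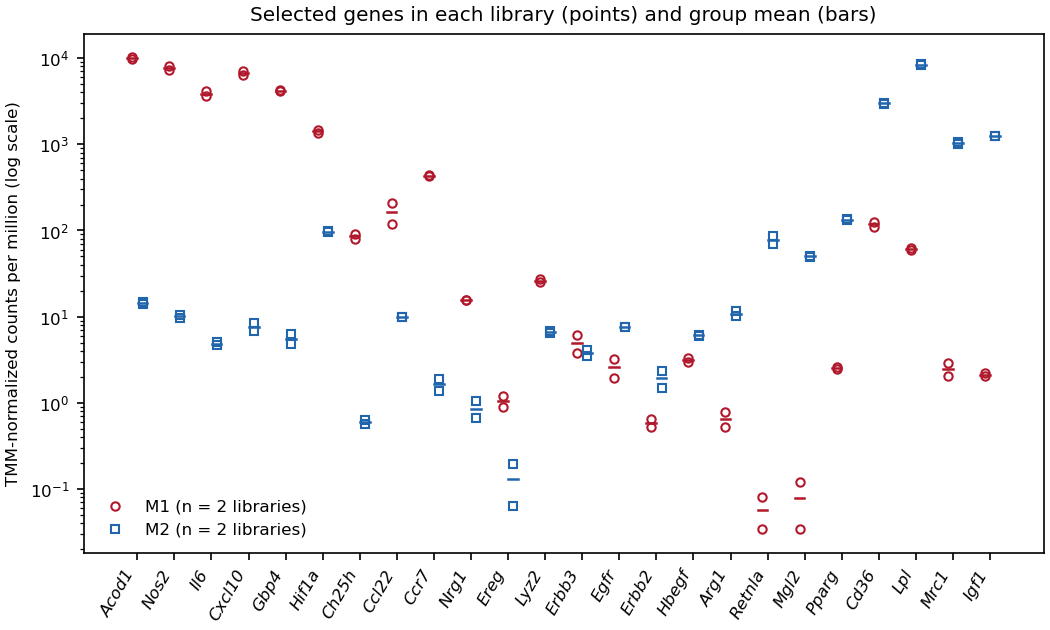
TMM-normalized CPM (log axis) of 24 genes in each of the 4 libraries; circles are M1 libraries, squares are M2 libraries and short bars are group means. Acod1, Nos2, Il6, Cxcl10 and Gbp4 have M1 means of 3866 (Il6) to 10040 CPM (Acod1) and M2 means of 4.88 to 14.5, while Lpl, Mrc1 and Igf1 have M2 means of 1035 (Mrc1) to 8354 CPM (Lpl).

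The classical program was higher in M1 in every measured list member. All 20 classical activation markers fell in M2 (camera adjusted p = 2.16e-10; adjusted p = 0.333 with an estimated correlation). Acod1, which makes itaconate, was 693-fold higher in M1, and Ptgs2, the inducible cyclooxygenase, reached 16968 ± 537 CPM there and was 556-fold higher. All 29 inflammatory cytokines and chemokines fell (4.56e-12; adjusted p = 0.333 with an estimated correlation), among them Il1b (710-fold) and Tnf (79.0-fold). All 38 interferon-stimulated genes fell (7.59e-16; adjusted p = 0.344 with an estimated correlation), with Ifi205 865-fold and Gbp4 763-fold higher in M1. All 19 NF-kappaB target and feedback genes fell (3.07e-09; adjusted p = 0.333 with an estimated correlation), led by the adaptor Traf1 (107-fold) and the regulator Nfkbiz (56.4-fold). The M1 libraries themselves were unequal in the interferon genes: 1 of the 38 was higher in replicate 2 than in replicate 1, and the median difference was -0.17 log2 units. The cytokines and chemokines differed the other way, with 17 of 26 higher in M1 replicate 2 and a median of 0.15. Of 22 interferon genes of at least 5 CPM in M2, 2 were higher in M2 replicate 2, with a median difference of -0.12.

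Alternative activation markers moved mostly upward. Of 26 measured, 20 rose and 6 fell (camera adjusted p = 4.90e-04, and adjusted p = 0.333 with an estimated correlation). Ear11 was on the list but was not found by that symbol, so it is not counted among them. Other names of the gene were not searched, so this does not show that it was unmeasured. Their median change was 5.22 log2 units, or 4.42 when Ccl17 and Chil4, which had no M1 count, stand at their lower bound. Chil3, the chitinase-like protein Ym1, was 330-fold higher, and the receptor Trem2 331-fold. Arg1, arginase 1, was 16.2-fold higher but stayed at 10.8 ± 1.03 CPM in M2, far below Chil3 (240.9 ± 6.89) and Mrc1 (1035 ± 32.5). The 6 that fell were Ch25h (141-fold), Ccl22 (16.4-fold), Tgm2, Il4ra (5.87-fold), Cish and Klf4. Ch25h makes an oxysterol, Ccl22 is a chemokine and Il4ra is the receptor chain shared by IL-4 and IL-13. The fall of Klf4 (-0.18 on the log2 scale) turned into a rise of 0.27 under total-count scaling and to a value of 0.00 under upper-quartile scaling, and that of Cish (-0.43) ended under total-count scaling (0.02). Ccl22 differed between the M1 libraries, at 119 and 206 CPM.

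Antigen presentation divided by class. All 20 genes of the MHC class I pathway fell in M2 (camera adjusted p = 3.07e-09; adjusted p = 0.333 with an estimated correlation). The H2-Q6 and H2-Q7 values, 277-fold and 149-fold higher in M1, are uncertain because near-identical class I genes can share reads. Tap1, the peptide transporter, was 23.9-fold and B2m, the shared light chain, 2.61-fold higher in M1. Of 12 class II genes, 7 rose, 2 fell and 3 were not called, and camera did not call the list (adjusted p = 0.368). The protease Ctss rose 3.73-fold, the peptide-loading gene H2-DMa 2.98-fold and the transactivator Ciita 2.55-fold. H2-Ob fell, with H2-Oa at 115 counts in M1 and 3 in M2 (ratio 55.2, interval 18.4 to 272), and these made the mean of the list negative at -0.25 against a median of 0.50. H2-Ab1 had 399 CPM in M1 and 327 in M2, and Cd74 had 1703 and 1665, and neither was called. H2-Ab1 passed as lower under RLE scaling (adjusted p = 0.0362), and Cd74 passed as higher under total-count scaling (log2 fold change 0.41, adjusted p = 0.0011). The M1 libraries differed in this list by a median of 0.32 log2 units, with 8 of 10 members higher in replicate 2. The count of class II genes that fell went from 2 to 4 without M1 replicate 1.

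Sensing and cell death genes followed the classical side. Of 20 measured pattern recognition receptors 15 fell, 4 rose and 1 was not called (camera adjusted p = 0.00299; adjusted p = 0.574 with an estimated correlation). Between the M1 libraries these receptors had a median difference of -0.21 log2 units, with 6 of 20 higher in replicate 2. Clec4e was 238-fold and the LPS co-receptor Cd14 89.2-fold higher in M1, whereas the scavenger receptor Cd36 was 25.2-fold and Tlr13 7.74-fold higher in M2. Of 18 inflammasome and cell death genes 15 fell, 2 rose and 1 was not called (1.31e-04; adjusted p = 0.333 with an estimated correlation). The sensor Nlrp3 was 97.4-fold higher in M1, while its adaptor Pycard was 3.37-fold higher in M2. Bcl2a1a, 56.7-fold higher in M1, belongs to a set of near-identical genes and is uncertain. Of 16 immune checkpoint and tryptophan catabolism genes 10 fell, 5 rose and 1 was not called (camera adjusted p = 0.204, or 0.0125 under total-count scaling). Lilrb4 was listed too but was not found by symbol, which does not show that the gene was unmeasured. Cd274, which encodes PD-L1, was 35.5-fold higher in M1 at 3832 ± 371 CPM, Pilra was 136-fold higher, and Ido1 was at least 108-fold higher. The inhibitory receptor Cd200r1 rose 11.3-fold and the galectin Lgals3 rose 7.96-fold in M2.

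Among the metabolic lists, camera called glycolysis lower and fatty acid oxidation higher in M2, and called neither with an estimated correlation. All 20 glycolysis and HIF1 target genes were lower in M2 (camera adjusted p = 1.53e-07; adjusted p = 0.333 with an estimated correlation), including Hif1a (14.6-fold) and Pfkfb3 (15.3-fold), which drives flux through phosphofructokinase; Gapdh was 3.50-fold lower in M2 than in M1. Under total-count scaling 17 of these 20 fell and 1, Pdk1, rose. Of 21 fatty acid oxidation and PPAR target genes 16 rose, 3 fell and 2 were not called (4.53e-04; adjusted p = 0.333 with an estimated correlation). Lpl, lipoprotein lipase, reached 8354 ± 115 CPM and rose 138-fold, and the nuclear receptor Pparg rose 52.3-fold. Slc25a20 and Ppard fell, by 1.19 and 1.13 on the log2 scale. The 32 nuclear-encoded genes on the list of the TCA cycle and respiratory chain split into 13 that rose, 9 that fell and 10 not called (camera adjusted p = 0.560). Idh2 and Idh1, isocitrate dehydrogenases, rose 10.9-fold and 10.4-fold. The Idh3 genes changed less: on the log2 scale Idh3a rose by 0.88 and Idh3g by 0.50, and Idh3b (0.11) was not called. Cox5a fell by 0.81 and Sdhd by 0.52 on that scale. The split of the list rested on the scaling: 28 rose and 1 fell under total counts, where camera called the list (0.0388), and 4 fell under upper-quartile scaling. The 9 that fell also became 4 without M2 replicate 1 and 5 without the filter on low counts.

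Arginine and polyamine genes split as well: 5 of 12 rose, 6 fell and 1 was not called (camera adjusted p = 0.374). Srm, spermidine synthase, rose 3.97-fold along with Arg1, and Arg2 fell with Nos2, being 19.4-fold higher in M1. Among 15 eicosanoid genes 9 rose and 6 fell (camera adjusted p = 0.578, direction upward, with a median of 0.57 log2 units), while fry gave the opposite direction (0.00147). Ptgs1, the constitutive cyclooxygenase, rose 153-fold and the prostaglandin-degrading Hpgd 59.0-fold, whereas the inducible Ptgs2 and the synthase Ptges (51.0-fold) were higher in M1. Of 21 oxidative stress and iron genes 15 fell, 2 rose and 4 were not called (0.00256; adjusted p = 0.333 with an estimated correlation), and adjusted over the list alone 16 fell. The iron-scavenging Lcn2 was 370-fold and the cystine transporter subunit Slc7a11 51.2-fold higher in M1. The transferrin receptor Tfrc rose 14.6-fold and Ftl1 2.29-fold in M2, and the 2 that rose became 4 without M1 replicate 2, 5 under upper-quartile and 6 under total-count scaling.

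Cholesterol genes were mixed. Of 19 synthesis genes 5 rose, 4 fell and 10 were not called (camera adjusted p = 0.797). Dhcr7, which acts at the end of the pathway, rose 5.58-fold. All 19 were higher in M1 replicate 2 than in M1 replicate 1, by a median of 0.40 log2 units, above the medians of 10000 random lists matched on expression. Between the M2 libraries the median difference was -0.09 and 3 of 19 were higher in replicate 2, below the medians of the random lists. Without M1 replicate 2 the number that rose was 11, without M2 replicate 2 it was 8, and without M1 replicate 1 the number that fell was 10. Under total-count scaling 13 rose. Of 10 efflux and LXR target genes 6 rose, 2 fell and 2 were not called (camera adjusted p = 0.366). The desaturases Scd1 and Scd2 rose 11.0-fold and 6.81-fold, and the LXR genes Nr1h3 and Nr1h2 fell by 1.01 and 0.99 on the log2 scale.

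Matrix, growth factor and fusion genes were largely on the M2 side. Of 26 matrix remodelling and growth factor genes 17 rose, 8 fell and 1 was not called (camera adjusted p = 0.0734, or 0.0262 without the filter on low counts). Besides Igf1, the protease inhibitor Timp2 rose 71.5-fold and the macrophage elastase Mmp12 44.0-fold, while Mmp25 was 544-fold and Mmp13 25.9-fold higher in M1. Of 11 stromal cell markers 9 rose and 2 fell (0.00549; adjusted p = 0.333 with an estimated correlation), so markers of another cell type moved with the matrix genes. Acta2 rose 45.3-fold to 161 ± 2.45 CPM, Postn 20.8-fold to 109 ± 3.59 CPM and Col1a1 to 554 ± 4.19 CPM (log2 fold change 3.81), and Dcn fell by 1.12 on the log2 scale. The stromal call ended under total-count scaling (adjusted p = 0.0532), where 1 of the stromal markers fell. Of 10 cell fusion and osteoclast genes 8 rose, 1 fell and 1 was not called (0.00549; adjusted p = 0.333 with an estimated correlation). Atp6v0d2, a proton pump subunit, rose 360-fold to 1016 CPM and Ctsk, cathepsin K, 15.4-fold, while Cd81 was 2.40-fold lower in M2 than in M1.

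The cell cycle list rose, with 21 of 28 higher, 3 lower and 4 not called (camera adjusted p = 0.00777; adjusted p = 0.333 with an estimated correlation), and adjusted over the list alone 22 rose. Cdc20 and Rrm2 rose 7.90-fold and 7.61-fold from under 1 CPM, while Ccne1 fell by 4.24 and Tyms by 1.58 on the log2 scale. Of 19 ERK feedback genes 12 fell, 5 rose and 2 were not called (0.0464; adjusted p = 0.333 with an estimated correlation). The phosphatase genes Dusp2 and Dusp5 were 40.3-fold and 24.6-fold higher in M1, and Dusp4 and Fos were 18.3-fold and 3.17-fold higher in M2. This call ended under RLE scaling (adjusted p = 0.0522), without M1 replicate 1 (0.0719) and without M1 replicate 2 (0.0525).

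Because the series concerns EGFR inhibition, the receptor family was examined whatever its values. Egfr itself (chromosome 11, 16752203 to 16918158, plus strand) was low and higher in M2: 2.61 ± 0.925 CPM in M1 and 7.54 ± 0.0390 in M2 (SD, n = 2 each), a log2 fold change of 1.51 (SE 0.18, edgeR adjusted p = 2.86e-06). This rests on 95 and 48 counts in the M1 libraries and 237 and 346 in the M2 libraries. Stromal cell markers also rose (9 of 11, with 2 falling), and which cells the Egfr counts came from was not tested. Erbb2 was 3.32-fold higher in M2 (32 counts in M1 and 156 in M2), and the ligand Hbegf was 1.96-fold higher. Erbb3 had 6.18 and 3.82 CPM in the M1 libraries and 4.05 and 3.54 in the M2 libraries and was not called (edgeR adjusted p = 0.0704), but it passed as lower in M2 without M1 replicate 2 (log2 fold change -0.72) and without M2 replicate 1 (-0.50). The ligands Ereg and Nrg1 were 7.31-fold and 17.4-fold higher in M1. Erbb4, Areg, Tgfa and Btc were too low to test: over both libraries of a group, Areg had 9 counts in M1 and 0 in M2, Tgfa 2 and 6, Btc 5 and 6, and Erbb4 0 and 1. Of 11 measured members of the EGFR list 7 rose, 2 fell and 2 were not called (camera adjusted p = 0.220), and the regulator Lrig1 rose 4.15-fold.

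Macrophage identity genes went both ways: of 21 measured, 8 rose, 11 fell and 2 were not called (camera adjusted p = 0.585), with a median of -0.35 and a mean of 0.11 log2 units. The transcription factor Cebpa rose 45.1-fold, whereas the phagocytic receptor Mertk was 8.21-fold higher in M1 and Ly6c2 8.72-fold. Lyz2 (chromosome 10, 117277331 to 117282321, minus strand), the lysozyme locus that carries Cre in these mice, was low in every library, with 736 and 671 counts in M1 and 204 and 317 in M2. It fell by 1.97 on the log2 scale (SE 0.10), from 26.3 ± 1.44 to 6.70 ± 0.261 CPM. Adgre1, which encodes F4/80, stood at 3089 ± 48.0 CPM in M1 and 1328 ± 51.8 in M2.

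Markers of other cell types went both ways. Of 8 neutrophil markers 4 rose, 2 fell and 2 were not called (camera adjusted p = 0.485): Ngp and Ltf rose 9.70-fold and 8.99-fold to under 3 CPM, S100a8 was 3.06-fold higher in M1, and Csf3r fell by 0.24 on the log2 scale, a call that ended under upper-quartile scaling and without M2 replicate 2 and turned upward under total-count scaling. Without M2 replicate 2 and under both of these scalings, 1 neutrophil marker fell. Of 7 dendritic cell markers 3 rose and 4 fell (camera adjusted p = 0.562), with Itgax, which encodes CD11c, 44.2-fold and Zbtb46 1.96-fold higher in M2 and the chemokine receptors Xcr1 (386-fold) and Ccr7 (271-fold) higher in M1. The Zbtb46 call ended without M2 replicate 1. Of 8 B cell markers 3 rose, 2 fell and 3 were not called (0.635), with Ebf1 9.97-fold and Ighm 1.82-fold higher in M2. Of 3 measured T and NK cell markers Cd4 rose 8.41-fold, and Cd247 and Lck fell, by 2.28 and 1.49 on the log2 scale. Of 3 mast cell and basophil markers Kit was 25.1-fold higher in M1, Mcpt8 rose on few counts (5 in M1 and 37 in M2), and Gata2 was not called; without M2 replicate 2, 0 of the 3 rose. The median of these 3 was 0.33 and their mean -0.67 log2 units. Of 4 erythroid genes edgeR called 0 and DESeq2 called 0, and 1, Hba-a1, had an unadjusted p under 0.05 (0.0391). Hba-a1 passed as higher in M2 without the filter on low counts, without M1 replicate 2, without M2 replicate 1 and under upper-quartile and total-count scaling, the last with Hbb-bs; its reads are uncertain because Hba-a2 is nearly identical. Of 5 endothelial markers 2 rose, 2 fell and 1 was not called (0.697), the median being 0.39 and the mean -1.04. Kdr (73.2-fold) and Pecam1 (19.3-fold) were higher in M1, and DESeq2 called 1 of the 2 that rose.

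Of the 13 mitochondrially encoded transcripts 3 rose, 3 fell and 7 were not called (camera adjusted p = 0.831). All 7 of at least 5 CPM were higher in M1 replicate 2 than in M1 replicate 1, by a median of 0.29 log2 units. mt-Nd2 rose 1.48-fold and mt-Co1 fell by 0.47 on the log2 scale, and mt-Nd5 fell by 0.34. These directions depended on scaling: under total-count scaling the mt-Co1 call ended and the value of mt-Nd5 turned to 0.11, with 6 of the 13 called as higher and 0 as lower. Upper-quartile scaling left 1 called as lower. Counts of mt-Co2 (1.64 CPM in M1) and mt-Nd3 (3.11 CPM), against 8969 CPM for mt-Co1, are uncertain because nuclear copies of mitochondrial sequence can share their reads.

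**Figure D2:**
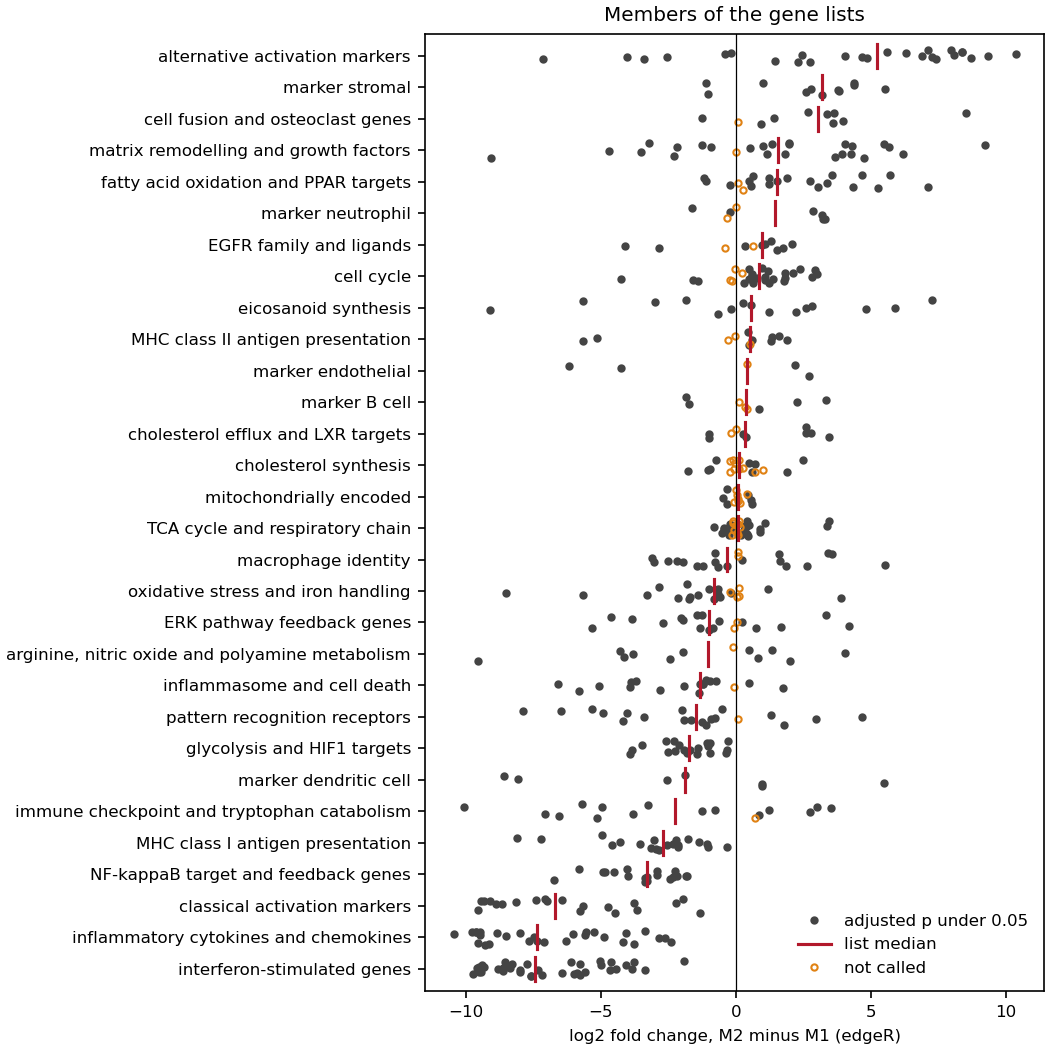
Log2 fold changes (M2 minus M1, edgeR) of the measured members of the 30 lists with at least 5 measured genes; filled points passed an adjusted p under 0.05, open points did not, and red bars are list medians of the fitted values. Interferon-stimulated genes (median -7.46) and inflammatory cytokines lie wholly to the left of 0, and alternative activation markers (median 5.22) lie mostly to the right.

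Over the 30 lists tested together, camera with a preset correlation of 0.01 called 15, 10 lower and 5 higher in M2. With an estimated correlation it called 0, with adjusted p from 0.333 to 0.945. That version has few degrees of freedom with 2 libraries per group and could hardly call a list, so its lack of calls decides nothing. Fry, which asks whether the genes of a list move on balance one way, called 25, and 30 when either direction counted. It does not set a list against the other genes, and 77.2% of all tested genes were called. Its calls therefore do not single these lists out. The counts adjusted over the list alone equalled those over all genes tested for 31 of the 33 lists, the exceptions being oxidative stress and iron handling and the cell cycle. The numbers and the sizes of rises and falls follow TMM scaling throughout.

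The authors' deposited table of the comparison was set beside the counts. It holds 5225 rows, 2373 higher in M1, 2851 higher in M2 and 1 with no fold change, each with a gene symbol and no gene ID. The base mean of 5166 rows in the authors' deposited table matched exactly 1 gene of the count table to a relative tolerance of 1e-07, and all 5166 had the sign of a DESeq2 refit of the matched gene. Of the 5072 matched genes that were also tested here, edgeR called 5070, all in the direction of the authors' deposited table. The printed symbols were a different matter. Up to a point in the order of the count table, soon after Gm21399 on chromosome 8, 2978 of 3018 matched rows in the authors' deposited table carried the symbol of the matched gene or an alias. Past it, 2108 of 2148 (98.1%) carried the symbol of the gene 1 row above in the count table. The row named Nos2 in the authors' deposited table has a log2 fold change of 3.25 (M1 over M2) and holds the values of Lgals9, and the values of Nos2 (9.56) stand under Lyrm9. For 1590 shifted rows the printed gene has a refit value of its own; in 505 of them its sign is opposite to the printed one, and in 1129 it differs by over 1 log2 unit. Of the 5225 rows, 302 have an adjusted p above 0.05 in the authors' deposited table. Fold changes elsewhere in the report come from the gene IDs of the count table.

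**Figure D3:**
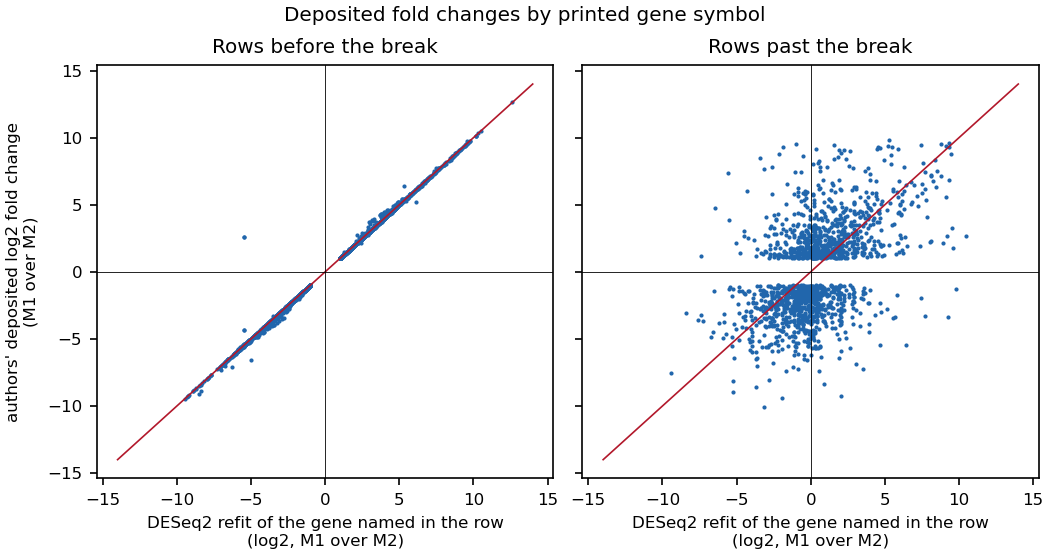
Log2 fold change (M1 over M2) in the authors' deposited table against a DESeq2 refit of the gene whose symbol the row prints, for 2982 rows before the break in the order of the count table (left) and 1599 rows past it (right); each point is a row and the red line marks equal values. Points follow the line on the left and scatter around it on the right.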

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

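The list members under upper-quartile and total-count scaling were run only after the results were seen, and all other alternatives were planned. Called genes numbered 8359 to 11912 over alternatives that kept the threshold, and 10166 to 11441 when 1 library was left out (5238 to 5860 higher and 4928 to 5581 lower); the lone library was then assumed to vary like the other group. With glmTreat beyond log2 1, which asks for a larger change by construction, 4840 were called, 2677 higher and 2163 lower. Under total-count scaling 3342 were lower.

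Camera called 15 lists, 0 with an estimated correlation, 25 with fry and 14 to 15 when 1 library was left out. The log2 fold changes of 124 genes were run under RLE, upper-quartile and total-count scaling, no filter, DESeq2, limma-voom and each library left out. Of these values, 1224 kept direction and call, 8 passed newly, 6 no longer passed and 2 reversed. The reversals, both under total-count scaling, were Csf3r (0.21) and mt-Nd5 (0.11), and by the shift of that scaling, 0.45 for the median gene, both would move upward. For eicosanoid synthesis the direction reversed with fry (0.00147); the cause was not tested. The list set tests were run with an estimated correlation, fry, RLE and total-count scaling, no filter and each library left out. Of these, 238 kept their call, 12 passed newly and 19 no longer passed, 15 of the last with an estimated correlation. Of the list counts, 314 higher and 318 lower counts stayed within 1.5 times and 16 and 12 did not. No paired analysis was possible because the replicate numbers were given in accession order. Erbb4, Areg, Tgfa and Btc had too few counts to test, and whether greater depth would change that was not tested.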

Other observations

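The tests of symbol families, of moved symbols, of shifted gene IDs, of reads shared with Lyz2 and of counts left in M2 were chosen after the data were seen, those of shifted gene IDs and shared reads before their own values were known. Grouping tested genes by symbol stem gave 143 families of at least 10 members. Camera called 12 of them, 6 higher and 6 lower in M2, and 0 with an estimated correlation (adjusted p = 0.937). The estimated version could hardly call a family with so few libraries. Of 49 genes with the stem Rpl, mostly large ribosomal subunit proteins, 44 rose, 1 fell and 4 were not called, with a median of 0.63 log2 units (1.07 under total-count scaling). Of 42 with the stem Rps, which also takes in Rps6k kinases, 34 rose and 5 fell. Collagen genes rose in 23 of 29 cases, with a median of 3.35 log2 units, among them Col6a1 (5.79) and Col6a3 (5.04), while Col9a3 fell by 3.30; stromal cell markers moved with them, 9 of 11 rising with a median of 3.17, and Col1a1, Col1a2 and Col3a1 are in both groups. Annexin genes rose in 8 of 10 cases, and Anxa1 went from 157 to 1728 CPM.

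In the other direction, all 10 Psmb genes of the proteasome fell, with a median of -1.07 log2 units under TMM and -0.62 under total-count scaling, and Psmb9, an interferon-induced subunit, by 2.95. Of 14 Psmd genes 12 fell, Psmd11 by 1.58, and Psmd8 rose by 0.21. Of 14 syntaxin genes 12 fell, led by Stx11 at -4.49, but the family median of -0.52 shrank to -0.07 under total-count scaling. Xist had 12771 to 21738 counts in every library, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 or 1.

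In the authors' deposited table, 98.1% of uniquely matched rows past the break carried the symbol of the gene 1 row above in the count table. The opposite error, gene IDs shifted under right symbols, is argued against: reading each count row as the preceding gene put 53.0% of counts past the break on protein-coding genes, against 98.6% under its own ID. A candidate explanation is that symbols moved by 1 row when they were joined to the table, a hypothesis found and tested on the same data. No biological explanation was tested.

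Lyz2 stood at 26.3 CPM in M1 and 6.70 in M2. Reads shared with other genes are argued against, since 0 of 1167 windows of 150 bases of the Lyz2 transcript occurred in transcripts of other genes. The share of macrophages in the cultures was not tested and stays open. Adgre1 stood at 3089 CPM in M1 and 1328 in M2, Cd68 at 119 and 1243, and Csf1r at 264 and 1640. The insertion of Cre at Lyz2 may lower the transcript and stays open too, because no library without Cre was analysed here.

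Genes abundant in M1 kept counts in M2: of 2245 genes of at least 100 CPM in M1, 0 lacked a count in M2. Among the 10 genes with the largest fold of those at the highest M1 level, the share of the M1 level left in M2 ran from 0.115% (Cxcl10) to 0.161% (Ccl5). As ratios of pooled counts, another measure than the fitted fold changes, Cxcl10 was 889-fold higher in M1 (counting interval 820 to 966) and Ccl5 629-fold (591 to 671). The lowest share was that of Cxcl11, 0.0682% on 11 counts, with an upper counting limit of 0.123%. Carry-over from the M1 libraries and expression in M2 cells cannot be told apart, because these genes were picked for their large folds and no library free of M1 material was analysed here. This limit covers the folds given above for Nos2, Il6, Il12b, Gbp4, Acod1, Il1b and Cxcl10, which are among these 10. It applies as well to the other large M1 folds given above, among them Cxcl11, BC023105, Bcl2l14, Gbp2b, Ifi205, Ptgs2 and Mmp25. The largest fold of genes of at least 1000 CPM in M2 was that of Igf1, 587-fold. Carry-over into M1 was not tested.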
